A study of Mus musculus with 30 samples.

How the data were processed

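RNA and open chromatin were measured in mouse CD4 T cells from spleen and lymph nodes of control (WT) animals and of animals labelled as a PKA knockout (KO). Per the labels, naive cells were enriched with a CD4 isolation kit and sorted. They were then profiled directly, after activation with antibodies to CD3 and CD28 for 3 days, or after a rest of 3 days in IL-7 followed by forskolin at 1 ug/mL for 4 h. RNA was measured by RNA-seq in all 3 conditions, and open chromatin by ATAC-seq in naive and activated cells. Every group held 3 libraries. The labels do not say whether the 3 libraries of a group came from separate animals, so p-values measure the spread between samples. They also do not name the PKA gene that was removed.

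For RNA the authors deposited counts per gene, as whole numbers without any scaling, in a table of the naive and activated libraries and another of the forskolin libraries. For ATAC the authors deposited a differential table for each state, on 110808 sites that are identical in both, of which 110684 are 400 bp wide. Each ATAC table holds counts per site and library. Its group means and fold, per the file headers and tested on the values, are log2 means of those counts without any scaling to library size, with WT minus KO as the fold. The p-value and FDR of the authors' test are deposited for each site, and the FDR equals the Benjamini-Hochberg adjustment of the deposited p-value. The labels give the mm10 genome build and no aligner, counter, peak caller or test. The design had assumed that the ATAC tables held folds on a scaled measure. Since the deposited fold is not scaled to depth, its sign was turned to KO minus WT and the deposited counts were also tested directly.

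Of 27179 features in the table of naive and activated libraries, 1314 had no gene symbol. They held 0.127% to 0.159% of a library's counts and were left out, which left 25865 symbols, and the forskolin table held 25860. RNA libraries held between 7665955 and 11968094 counts, and ATAC libraries between 18522373 and 25318916 counts in sites. A gene with 0 counts in an RNA library was below 3 counts, which is 0.251 to 0.391 CPM (counts scaled to the same total in every library) depending on the library. Where every library of a group held 0 counts, folds were computed against a floor of 3 counts over the group and given as lower bounds. Floors cover counting error only.

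RNA comparisons used edgeR 4.0.16 in R 4.3.3 with filterByExpr, TMM scaling, a robust quasi-likelihood fit and the quasi-likelihood test, and Benjamini-Hochberg adjustment at 0.05. Naive and activated libraries shared a single fit with a mean per group, from which the genotype difference in each state, the activation difference in each genotype and their interaction were taken. The 6 forskolin libraries had a fit of their own. There were 11980 genes tested in the shared fit and 11658 in the forskolin fit. Log2 fold changes are KO over WT with SE unless stated otherwise. Gene levels are the mean CPM with SD over 3 libraries.

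A total of 38 gene lists were fixed before the data were examined, as were the comparisons, tests and alternatives. Lists with at least 5 tested genes were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over the lists, with 4 lists of the target, the core genes and sample quality kept outside that family. The camera test was repeated with an estimated correlation, and fry was run beside it. Counts of list members past the test are given over all genes tested and adjusted over the list alone.

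Named genes were chosen by rule. They are Prkaca, Prkacb and a core list on Th1 cells and IL-12, whatever their result. To these were added the 8 largest changes in each direction among genes past the test with at least 5 CPM in the higher group and no overlap between groups, leaving out unnamed gene models, receptor segments and sex-linked genes. Lists past the list test, or with at least 3 members past the gene test, each gave the 4 members with the smallest p. For ATAC the 5 sites with the largest deposited fold in each direction were named, with the sites at core genes. Cd4, the ATAC clusters on chromosomes 3 and 18, and the genes given for the overlap of conditions were chosen after their values were seen.

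The main ATAC calls are the authors' deposited FDR under 0.05. An edgeR quasi-likelihood test on the deposited counts, with TMM, was chosen after seeing the data. Sites were tied to genes through the RefSeq gene spans of GRCm38.p6, within 10 kb on either side, because the annotation used carried no strand. Of the symbols in the RNA tables, 23889 and 23789 were found there. Genes with a called site and genes past the RNA test were compared with Fisher's exact test, two-sided, among tested genes with at least 1 site. Overlaps of RNA comparisons used the same test.

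Alternatives were RLE and upper-quartile scaling, other filters on low counts, FDR 0.01, a minimum absolute log2 fold change of 1, limma-voom, DESeq2 1.42.0, a fit on the compared groups only, each library left out in turn, and a replicate block. For ATAC they included limma on the scaled counts. Correlation of libraries that share a replicate number was checked after removing group means. Each set held 3 pairs. The correlation ran from 0.236 to 0.557 for activated KO with WT RNA and from 0.126 to 0.360 for activated with naive KO RNA. For KO with WT ATAC it ran from 0.182 to 0.352 in naive and from 0.106 to 0.343 in activated cells. All passed 0.1, the limit set for pairs. Libraries of unlike number reached 0.254 and 0.123 in these RNA sets, and 0.0457 and 0.139 in naive and activated ATAC. Only naive ATAC thus set same-number libraries clearly apart, and pairs are not established in the other sets. Libraries of replicate 1 were male and the others female in the naive and activated RNA of both genotypes. With forskolin, replicate 3 was male and the others female in both genotypes. Every RNA group thus held libraries of both sexes, and so of more than a single animal. A likeness by number in the RNA sets can also come from sex. The test for CREB motifs in sites was not run, since a genome sequence was not used here. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and SciPy 1.17.1, and plots were drawn with matplotlib 3.10.9. The fits were tested on simulated data.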

Results

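The study asks how protein kinase A (PKA), the kinase activated by cyclic AMP, and its target transcription factor CREB shape the response of CD4 T cells to IL-12 and their choice of the Th1 fate. RNA-seq and ATAC-seq libraries were made from naive and activated CD4 T cells of WT and KO mice, and RNA-seq libraries from cells treated with forskolin, which activates adenylyl cyclase and so raises cyclic AMP. Every group of genotype, condition and assay held 3 libraries. RNA libraries of naive cells held 8284857 to 11305538 counts in WT and 8851649 to 9627420 in KO. Those of activated cells held 10550111 to 11217090 in WT and 10300044 to 11968094 in KO, and those of forskolin-treated cells 7665955 to 9312606 in WT and 9404642 to 11802115 in KO. ATAC libraries of naive cells held 18522373 to 23858964 counts in sites, and those of activated cells 20622289 to 25318916.

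Prkaca, which encodes the catalytic subunit alpha of PKA, was lower in KO in all 3 conditions. In naive cells it stood at 2.43 ± 0.307 CPM in KO and 36.5 ± 4.46 CPM in WT (SD, n = 3), a log2 fold change of -3.91 ± 0.16 (edgeR quasi-likelihood test, adjusted p = 1.64e-10). In activated cells it stood at 1.06 ± 0.283 CPM in KO and 47.9 ± 5.66 CPM in WT, a log2 fold change of -5.49 ± 0.18 (adjusted p = 6.05e-13). With forskolin it stood at 3.18 ± 0.617 CPM in KO and 35.0 ± 2.27 CPM in WT, a log2 fold change of -3.45 ± 0.13 (adjusted p = 7.79e-19). Prkacb, which encodes the catalytic subunit beta, was at 122 CPM in naive KO and 123 CPM in naive WT cells (adjusted p = 1) and at 55.0 and 54.0 CPM in activated cells (adjusted p = 0.833). With forskolin it was lower in KO, at 185 against 209 CPM (log2 fold change -0.17 ± 0.04, adjusted p = 0.000299). Among 7 measured PKA subunit and inhibitor genes, 4 were lower in activated KO cells and none was higher. Besides Prkaca these were Prkx at -0.41, Prkar1a at -0.31 and Prkar2a at -0.30 on the log2 scale, which lost their calls with some libraries left out. Adjusted p reached 0.0568 for Prkx (without WT replicate 1 or KO replicate 3), 0.0611 for Prkar1a (without WT replicate 2 or 3, or KO replicate 1 or 2) and 0.0569 for Prkar2a (without WT replicate 3, or KO replicate 2 or 3).

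**Figure D1:**
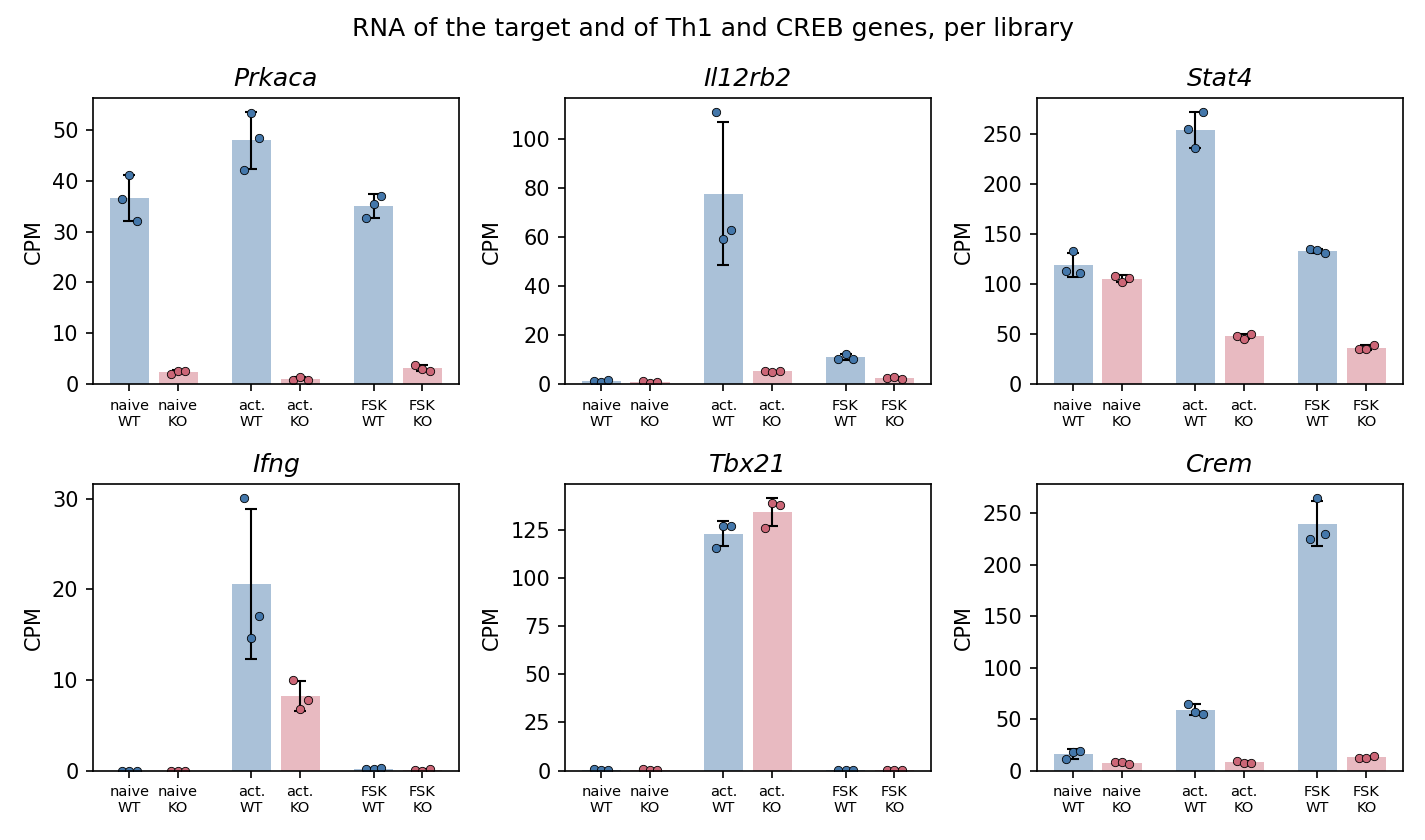
Expression of Prkaca, Il12rb2, Stat4, Ifng, Tbx21 and Crem in CPM, by condition and genotype (act., activated; FSK, forskolin). Bars are means, error bars the SD over 3 libraries and points the libraries; Il12rb2 and Stat4 in activated cells were lower in every KO library than in every WT library, while Tbx21 overlapped in level between genotypes.

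The activation of WT cells, the background for the genotype comparisons, changed most measured genes. Il12rb2 and Il12rb1, the receptor chains for IL-12, rose from 1.27 ± 0.296 to 77.9 ± 29.0 CPM and from 3.88 ± 0.574 to 229 ± 17.3 CPM (SD, n = 3). Stat4, the transcription factor downstream of this receptor, rose from 119 ± 12.2 to 254 ± 18.1 CPM, and Tbx21, which encodes the Th1 master regulator T-bet, rose from 0.397 ± 0.218 to 123 ± 6.60 CPM. Prkaca rose by a log2 fold change of 0.38 ± 0.12 (adjusted p = 0.00547). Ifng, the signature Th1 cytokine, had 0 counts in every naive library and reached 20.6 ± 8.31 CPM after activation. All 30 measured cell cycle genes rose, among them the proliferation marker Mki67, from 4.89 ± 1.07 to 680 ± 11.1 CPM (camera adjusted p = 1.18e-11, and adjusted p = 0.0586 with an estimated correlation). The 24 genes of cholesterol and lipid synthesis rose as well (camera adjusted p = 3.23e-07, and adjusted p = 0.192 with an estimated correlation). So did all 17 glycolysis genes (camera adjusted p = 9.45e-07, and adjusted p = 0.173 with an estimated correlation). Of 23 genes of T cell activation 21 rose, among them the IL-2 receptor chain gene Il2ra at 8.50 ± 0.14 and the transferrin receptor gene Tfrc at 5.14 ± 0.09 (camera adjusted p = 1.89e-07). Of 22 genes of naive and quiescent cells 20 fell, among them the egress receptor gene S1pr1 at -6.17 ± 0.11 and Klf3 at -3.55 ± 0.08 (camera adjusted p = 2.2e-07). In total 5067 of 11980 genes rose and 4830 fell.

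Activated KO cells were compared with naive KO cells, to follow the same genes in the KO. The interaction test called 12 gene lists that moved differently from WT in this step, of which 2 passed with an estimated correlation. Prkaca fell from its low naive level (log2 fold change -1.20 ± 0.26, adjusted p = 0.00041). Il12rb2 rose from 0.878 ± 0.381 to 5.29 ± 0.136 CPM, and Stat4 fell from 105 ± 3.39 to 47.8 ± 2.67 CPM (SD, n = 3). Tbx21 rose from 0.418 ± 0.137 to 135 ± 7.19 CPM, and Il12rb1 from 6.66 ± 1.83 to 223 ± 18.4 CPM. Crem, a CREB-family gene that CREB itself induces, stood at 8.12 ± 1.09 CPM after activation and 7.58 ± 0.777 CPM before (adjusted p = 0.629). All 30 cell cycle genes rose (camera adjusted p = 8.64e-12, and adjusted p = 0.0799 with an estimated correlation), as did 21 of 23 genes of T cell activation (camera adjusted p = 5.9e-07). The list of 28 cAMP-CREB target genes, with 15 higher and 6 lower, did not pass the list test (camera adjusted p = 0.125). In total 5065 genes rose and 4772 fell.

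The comparison of activated KO with activated WT cells asks which genes depend on the deleted gene once the T cell receptor has been engaged. The IL-12 pathway was lower in KO at its signal-specific chain and its transcription factor. Il12rb2 stood at 5.29 ± 0.136 CPM in KO against 77.9 ± 29.0 CPM in WT (SD, n = 3), a log2 fold change of -3.88 ± 0.24 (edgeR quasi-likelihood test, adjusted p = 2.5e-07). Stat4 stood at 47.8 ± 2.67 CPM against 254 ± 18.1 CPM, a log2 fold change of -2.41 ± 0.08 (adjusted p = 1.2e-12). Il12rb1 was at 223 ± 18.4 CPM in KO and 229 ± 17.3 CPM in WT (adjusted p = 0.837), and Tbx21 at 135 ± 7.19 and 123 ± 6.60 CPM (adjusted p = 0.298). Ifng was lower at 8.20 ± 1.63 CPM against 20.6 ± 8.31 CPM (log2 fold change -1.32 ± 0.29, adjusted p = 0.0158). Its adjusted p ran from 3.9e-05 to 0.0785 over the alternatives. The call of Ifng was lost, with adjusted p above 0.05, without a low-count filter and without KO replicate 2 or 3. Of 20 measured Th1 genes 9 were lower and 2 higher, or 9 and 3 adjusted over the list alone (camera adjusted p = 0.00294, and adjusted p = 0.138 with an estimated correlation). Gzmb, the gene of the cytotoxic protease granzyme B, stood at 7.0 ± 3.16 CPM against 547 ± 404 CPM, and the transcription factor gene Bhlhe40 at 127 ± 5.58 CPM against 427 ± 53.8 CPM. Of 13 genes of IL-12 and IL-18 receptor signalling 6 were lower and 2 higher, or 6 and 3 adjusted over the list alone (camera adjusted p = 0.0298, and adjusted p = 0.169 with an estimated correlation). The higher ones included Il18r1, a chain of the IL-18 receptor, with a log2 fold change of 1.41 ± 0.14.

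Targets of CREB were the list with the smallest camera adjusted p in this comparison. Of 28 measured cAMP-CREB target genes 19 were lower in activated KO cells and 3 higher, or 24 and 3 adjusted over the list alone (camera adjusted p = 5.75e-18, and 0.00147 with an estimated correlation). Crem stood at 8.12 ± 1.09 CPM in KO against 59.1 ± 5.31 CPM in WT, Nr4a1, an orphan nuclear receptor gene induced by receptor signals, at 232 ± 12.9 against 662 ± 75.6 CPM, and the phosphatase gene Dusp4 at 53.5 ± 2.13 against 298 ± 21.7 CPM (SD, n = 3). Among phosphodiesterases, which break down cyclic AMP, Pde4d was at -3.42 ± 0.17, Pde3b at -3.09 ± 0.14 and Pde4b at -1.15 ± 0.09 on the log2 scale. The list of 23 genes of phosphodiesterases and cAMP production held 7 lower and 2 higher ones, or 7 and 3 adjusted over the list alone (camera adjusted p = 0.00346, and adjusted p = 0.132 with an estimated correlation). Of 23 genes of T cell activation 14 were lower and 3 higher, the same counts adjusted over the list alone (camera adjusted p = 1.8e-05, and 0.0157 with an estimated correlation). Among them were the costimulatory receptor genes Tnfrsf4 at -1.28 ± 0.09 and Tnfrsf18 at -1.26 ± 0.08, the checkpoint receptor gene Ctla4 at -1.84 ± 0.11, and Il2, the T cell growth factor, at 145 ± 4.88 CPM against 298 ± 25.3 CPM. Of 15 genes of dissociation and heat shock stress, a quality list outside the correction, 4 were lower and 1 higher. The lower ones were Fos at -1.88 ± 0.24, Ier3 at -1.72 ± 0.23, Jun at -1.10 ± 0.20 and Junb at -0.39 ± 0.07, of which Fos and Junb are also cAMP-CREB target genes. The list summed to 5514 ± 58.0 CPM in KO and 6264 ± 187 CPM in WT.

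**Figure D2:**
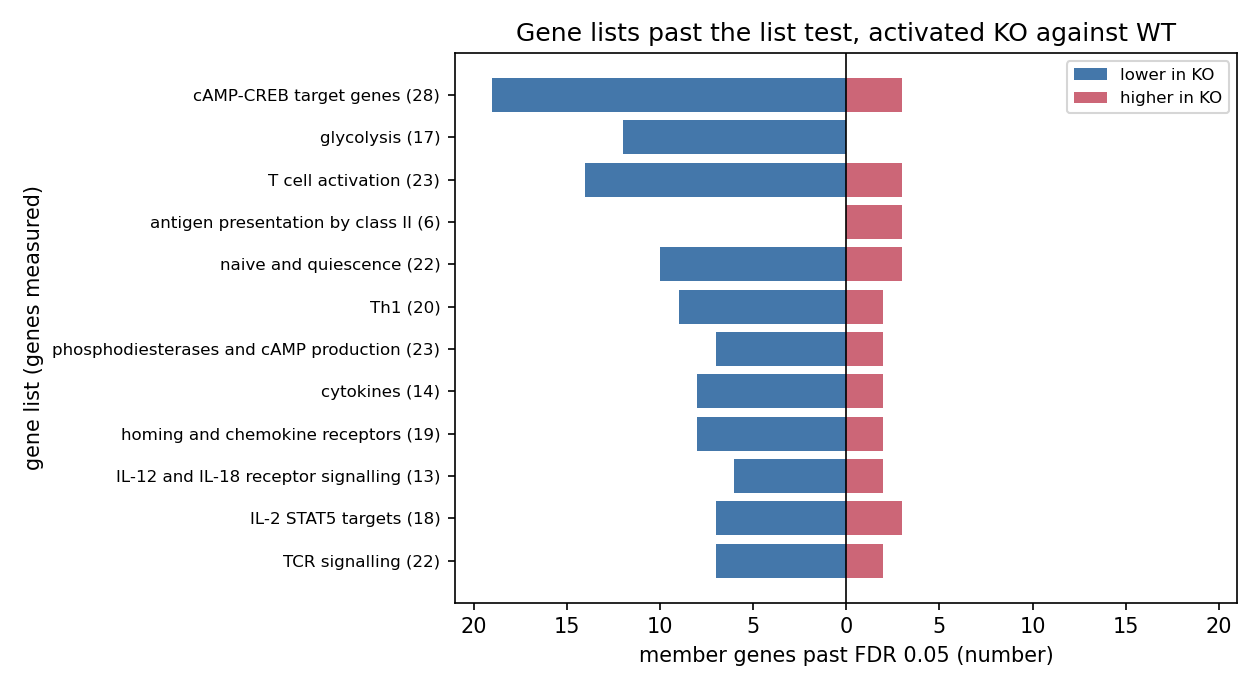
Number of member genes past the gene test (FDR under 0.05) that were lower (left) or higher (right) in activated KO than WT cells, for each of the 12 gene lists past the camera test. Labels give the number of genes measured; the cAMP-CREB target genes have 19 lower and 3 higher members, and the class II list alone has none lower.

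Metabolic, homing and cytokine genes also differed between activated KO and WT cells. Of 17 glycolysis genes 12 were lower and none higher, or 14 lower adjusted over the list alone, with the lactate transporter gene Slc16a3 at -1.15 ± 0.10 and the hexokinase gene Hk2 at -0.62 ± 0.09 (camera adjusted p = 1.1e-06, and adjusted p = 0.152 with an estimated correlation). Of 22 genes of naive and quiescent cells 10 were lower and 3 higher, or 12 and 3 adjusted over the list alone (camera adjusted p = 0.00244, and adjusted p = 0.132 with an estimated correlation). The lymph node homing receptor gene Ccr7 was at 234 ± 6.45 CPM in KO against 1351 ± 63.4 CPM in WT, and the chromatin organiser gene Satb1 at 58.9 ± 7.01 against 306 ± 9.72 CPM (SD, n = 3). Of 19 homing and chemokine receptor genes 8 were lower and 2 higher, or 8 and 3 adjusted over the list alone (camera adjusted p = 0.0122, and adjusted p = 0.132 with an estimated correlation). Of 14 cytokine genes 8 were lower and 2 higher, with the same counts adjusted over the list alone (camera adjusted p = 0.00469, and adjusted p = 0.132 with an estimated correlation). Il3 was at 0.211 ± 0.147 CPM against 15.7 ± 4.96 CPM, and Csf2, which encodes GM-CSF, at 4.20 ± 1.27 against 27.0 ± 8.49 CPM, while Ltb, the lymphotoxin beta gene, was higher at 320 ± 3.56 against 105 ± 9.01 CPM. Of 22 T cell receptor signalling genes 7 were lower and 2 higher, or 7 and 3 adjusted over the list alone (camera adjusted p = 0.0382, and adjusted p = 0.132 with an estimated correlation, with the call lost with a replicate block and without KO replicate 3), among them the ubiquitin ligase gene Cblb at -1.99 ± 0.08. Of 18 IL-2 and STAT5 target genes 7 were lower and 3 higher, or 10 and 4 adjusted over the list alone (camera adjusted p = 0.0382, adjusted p = 0.457 with an estimated correlation and 0.110, 0.0724 and 0.0523 without WT replicate 1, KO replicate 2 and KO replicate 3), with Cish at -0.98 ± 0.11 and Socs2 at 1.28 ± 0.10.

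Genes of antigen presentation by class II molecules were higher in activated KO cells. Cd74, the invariant chain gene, stood at 245 ± 10.7 CPM in KO against 107 ± 14 CPM in WT, and H2-Aa, a class II chain gene, at 9.99 ± 2.01 against 1.97 ± 0.830 CPM (SD, n = 3). Of the 6 measured genes 3 were higher, or 5 adjusted over the list alone (camera adjusted p = 0.00197, and adjusted p = 0.152 with an estimated correlation). Ighm, the B cell immunoglobulin heavy chain gene, was at 170 ± 13.1 CPM in KO and 112 ± 11.1 CPM in WT, and Ms4a1, the B cell gene of CD20, at 1.05 ± 0.327 and 0.0906 ± 0.0911 CPM. Other genes with large differences were Ramp3, which encodes a receptor-modifying protein, at -6.54 ± 0.25, Ccn1 at -5.78 ± 0.22 and the neurotrophin receptor gene Ntrk3 at -5.44 ± 0.35, with Slc30a3 at 3.34 ± 0.33, Spib, a transcription factor gene of B cells and dendritic cells, at 2.66 ± 0.38, Wnt3 at 2.47 ± 0.27 and the chemokine gene Ccl22 at 2.13 ± 0.36. No gene of 30 in the cell cycle list and none of 20 in the ribosome biogenesis list passed the gene test. In total 1083 genes were lower and 706 higher in activated KO cells, of which 259 and 177 by at least 1 on the log2 scale. The split was 843 lower and 987 higher with upper-quartile scaling, and 1151 genes passed without KO replicate 3.

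Naive cells, compared to ask what the KO changes before activation, differed in 29 of 11980 genes, with 14 lower and 15 higher in KO. Prkaca was the gene with the largest difference. Pde3b stood at 78.7 ± 10.1 CPM in KO against 246 ± 40.2 CPM in WT, and the CREB-responsive gene Fosl2 had a log2 fold change of -1.13 ± 0.15 (SD and SE, n = 3, edgeR quasi-likelihood test, adjusted p = 3.99e-06 and 0.00179). Pde4d was at -0.96 ± 0.14 and Crem at -1.07 ± 0.19 (adjusted p = 0.00708 and 0.0179), with levels of 7.58 ± 0.777 CPM against 15.9 ± 4.50 CPM for Crem. The call of Crem was lost without any 1 of WT replicates 2 and 3 and the KO libraries (adjusted p up to 0.170), and that of Pde4d without WT replicate 3 or any 1 KO library (adjusted p up to 0.0880). Of 28 cAMP-CREB target genes these 4 were lower, or 6 adjusted over the list alone (camera adjusted p = 0.00204, adjusted p = 0.105 with an estimated correlation and 0.119 without KO replicate 2). Cd74 was higher at 17.5 ± 6.27 CPM against 4.37 ± 0.898 CPM. That call was lost without WT replicate 2 or 3 and without a low-count filter (adjusted p up to 0.0777). Iigp1, an interferon-inducible GTPase gene, was higher at 98.6 ± 10.7 against 44.4 ± 6.53 CPM. It lies at 60373616 to 60392634 on chromosome 18. Between 60 and 61 Mb there, 14 of 72 tested ATAC sites were higher in naive KO cells and 0 lower. A local effect of that region was not tested. The class II list had 2 of 6 genes higher, or 6 adjusted over the list alone (camera adjusted p = 4.12e-12, and adjusted p = 0.0543 with an estimated correlation). In total 8 lists passed camera, 6 higher and 2 lower in KO. Also higher were Treg and Tfh genes (camera adjusted p = 0.000265 each), p53 targets and apoptosis (0.00204), cholesterol and lipid synthesis (0.0334) and cell cycle (0.0437). The CREB family and coactivators were lower (camera adjusted p = 0.019). With an estimated correlation 0 lists passed. Summed haemoglobin and other erythroid markers were at 12.7 CPM in KO and 4.63 CPM in WT, and summed B cell markers at 327 and 331 CPM. Stat4 was at 105 ± 3.39 CPM in naive KO and 119 ± 12.2 CPM in naive WT cells (adjusted p = 0.95), and Il12rb2 at 0.878 ± 0.381 and 1.27 ± 0.296 CPM (adjusted p = 1). The number of genes past the test fell to 11 without WT replicate 2, 17 without KO replicate 1 and 12 without KO replicate 3, and was 59 with DESeq2.

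Whether the genotype difference itself changed with activation was tested as the interaction. For Stat4 the difference in log2 fold change, activated minus naive, was -2.23 ± 0.11 (edgeR quasi-likelihood test, adjusted p = 1.49e-09), and for Il12rb2 it was -3.38 ± 0.71 (adjusted p = 0.0177, at most 0.166 over the alternatives). Crem had -1.79 ± 0.25 (adjusted p = 0.000367), Nr4a1 -1.15 ± 0.21 (adjusted p = 0.00567) and Prkaca -1.58 ± 0.29 (adjusted p = 0.00286). Il12rb1 had -0.81 ± 0.22 (adjusted p = 0.0502) and Tbx21 0.06 ± 0.50 (adjusted p = 0.991). Of 28 cAMP-CREB target genes 11 had a lower difference in activated cells and none a higher one, or 18 and 1 adjusted over the list alone (camera adjusted p = 8.3e-17, and 0.00187 with an estimated correlation). Of 23 genes of T cell activation 9 were lower and none higher, or 12 and 2 adjusted over the list alone (camera adjusted p = 6.73e-06, and 0.011 with an estimated correlation). In total 443 genes passed, 302 with a lower and 141 with a higher difference in activated cells. The split was 257 and 192 with upper-quartile scaling, and 290 genes passed without activated KO replicate 2.

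Forskolin treatment asks which genes depend on the deleted gene when cyclic AMP is raised directly. Crem stood at 12.9 ± 0.677 CPM in KO against 240 ± 21.8 CPM in WT, and Fosl2 at 6.0 ± 4.21 against 802 ± 33.7 CPM (SD, n = 3). Pde4d was at 102 ± 2.66 against 635 ± 17.2 CPM and Pde3b at 155 ± 9.31 against 847 ± 35.3 CPM. Stat4 was lower at 36.6 ± 2.38 against 133 ± 2.15 CPM (log2 fold change -1.86 ± 0.06, edgeR quasi-likelihood test, adjusted p = 2.72e-21), and Il12rb2 at 2.59 ± 0.455 against 11.1 ± 1.25 CPM (log2 fold change -2.10 ± 0.19, adjusted p = 3.97e-10). Il12rb1 was higher, at 2.96 ± 0.866 against 0.475 ± 0.204 CPM (log2 fold change 2.58 ± 0.41, adjusted p = 6.75e-06). Ifngr1, which encodes a chain of the interferon gamma receptor, was at 93.4 ± 4.37 against 1171 ± 23.9 CPM, and the salt-inducible kinase gene Sik1 at 12.6 ± 0.940 against 114 ± 4.25 CPM. Of 21 cAMP-CREB target genes 15 were lower and 2 higher, or 16 and 2 adjusted over the list alone (camera adjusted p = 5.93e-09, and 0.0455 with an estimated correlation). No forskolin-free cells were in this set, so the values compare genotypes under forskolin and not the response to it.

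Genes of ribosome biogenesis, of lipid synthesis and of IL-2 and STAT5 signalling were higher in forskolin-treated KO cells. All 20 measured ribosome biogenesis genes were higher, with the same count adjusted over the list alone (camera adjusted p = 2.75e-12, and 0.0313 with an estimated correlation), for example Rrp12 at 1.77 ± 0.09. Of 23 genes of cholesterol and lipid synthesis 21 were higher, with the same count adjusted over the list alone (camera adjusted p = 4.47e-11, and 0.0313 with an estimated correlation). Of 18 IL-2 and STAT5 target genes 14 were higher and 1 lower, or 14 and 2 adjusted over the list alone (camera adjusted p = 4.51e-05, and adjusted p = 0.325 with an estimated correlation), among them the IL-2 receptor chain gene Il2ra at 2.58 ± 0.10, the anti-apoptotic gene Bcl2 at 1.25 ± 0.04 and the cytokine signalling inhibitor gene Socs2 at 3.61 ± 0.24. Of 24 interferon-stimulated genes 12 were higher and 1 lower, with the same counts adjusted over the list alone (camera adjusted p = 0.00511, and adjusted p = 0.405 with an estimated correlation). Of 17 genes of the unfolded protein and amino acid response 11 were higher and 1 lower, with the same counts adjusted over the list alone (camera adjusted p = 0.0134, and adjusted p = 0.211 with an estimated correlation). Of 7 cytokine genes 6 were higher and 1 lower (camera adjusted p = 0.0196, adjusted p = 0.325 with an estimated correlation and 0.0511 without KO replicate 1). Of 13 Th1 genes 8 were lower and 2 higher (camera adjusted p = 0.0358, and adjusted p = 0.325 with an estimated correlation), again the same counts adjusted over either list alone. The Th1 list lost its call without any 1 library other than KO replicate 3, with adjusted p up to 0.126. Summed B cell markers were at 334 ± 5.34 CPM in KO and 187 ± 12.3 CPM in WT (SD, n = 3), and Cd74 stood at 36.9 CPM in KO replicate 1 against 12.4 and 7.38 CPM in the other KO libraries. In total 2294 of 11658 genes were higher and 2190 lower in KO, and 4031 genes passed without KO replicate 1.

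Genes that differed in activated cells overlapped with those that differed under forskolin. Of 10998 genes tested in both, 380 were lower in KO in both against 183 by chance (Fisher's exact test, two-sided, odds ratio 3.18, p = 2.15e-54), and 248 were higher in both against 122 by chance (odds ratio 2.98, p = 1.33e-33 by the exact test). Genes with opposite directions were fewer than by chance, with 147 against 193 and 63 against 116. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.271 and a Spearman rho of 0.184. Genes lower in both included Ramp3, Crem, Pde4d, Pde3b, Fosl2, Il12rb2, Gzmb and Cblb, and genes higher in both included Socs2, Setbp1 and the lymphotoxin gene Lta. Of the 14 genes lower in naive KO cells 12 were lower in activated and 13 in forskolin-treated KO cells.

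**Figure D3:**
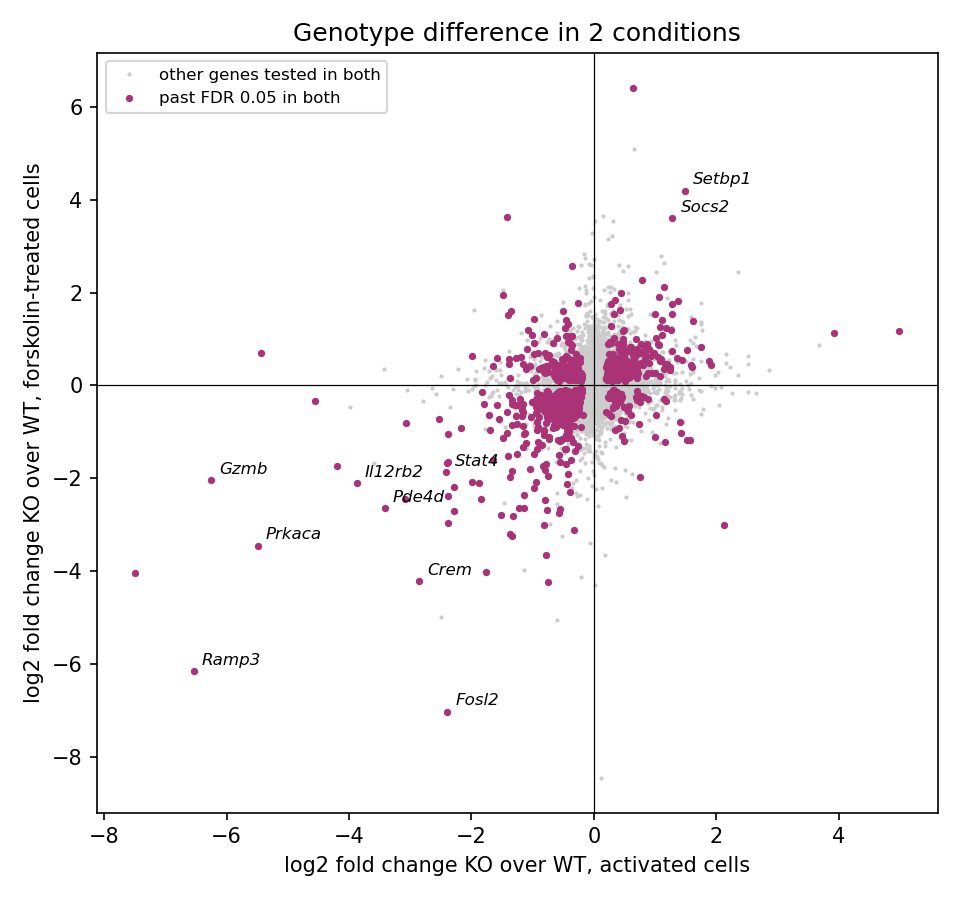
Log2 fold change of KO over WT in activated cells (horizontal) and forskolin-treated cells (vertical) for the 10998 genes tested in both; each point is a gene and coloured points passed FDR 0.05 in both. The coloured points hold 380 genes lower in both and 248 higher in both.

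ATAC-seq asks whether the KO also changes open chromatin. In activated cells the authors' deposited table called 5713 of 110808 sites, 5138 lower and 575 higher in KO. Its folds are not scaled to library size, and the log2 ratio of total counts, KO over WT, was -0.15. All 5713 called sites had an absolute log2 difference of at least 1 there. The edgeR quasi-likelihood test on the deposited counts, scaled with TMM, called 37350 sites, 21287 lower and 16063 higher, of which 8113 and 2310 by at least 1 on the log2 scale. With upper-quartile scaling the split was 17891 lower and 26679 higher, and the median over sites was 0.12 on the log2 scale against 0.02 with TMM. At Il12rb2 the authors' deposited table called 2 sites lower in KO. They lie within the gene on chromosome 6, at 67367114 to 67367514 and at 67373650 to 67374050, with log2 differences of -1.64 and -2.11 in the authors' deposited table. At Stat4 on chromosome 1 it called 3 sites lower, and the site at 52055927 to 52056327 had 3.00 ± 0.729 CPM in KO against 18.3 ± 2.28 CPM in WT (SD, n = 3). By the edgeR test 9 of 16 sites within 10 kb of Il12rb2 were lower and 1 higher, and 10 of 23 near Stat4 were lower and 3 higher. Tbx21 had 12 sites, none called in the authors' deposited table, and 2 were lower and 1 higher by the edgeR test. Crem and Nr4a1 had 1 and 2 lower sites in the authors' deposited table, and Prkaca none. By the edgeR test Crem had 3 lower sites, Nr4a1 had 6 lower and 1 higher, and Prkaca had 1 higher. The largest lower sites of the authors' deposited table lay 421 kb from Htr2a, 127 kb from Foxp2 and 176 kb from Sema3d, at log2 differences of -5.35, -5.03 and -4.99.

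**Figure D4:**
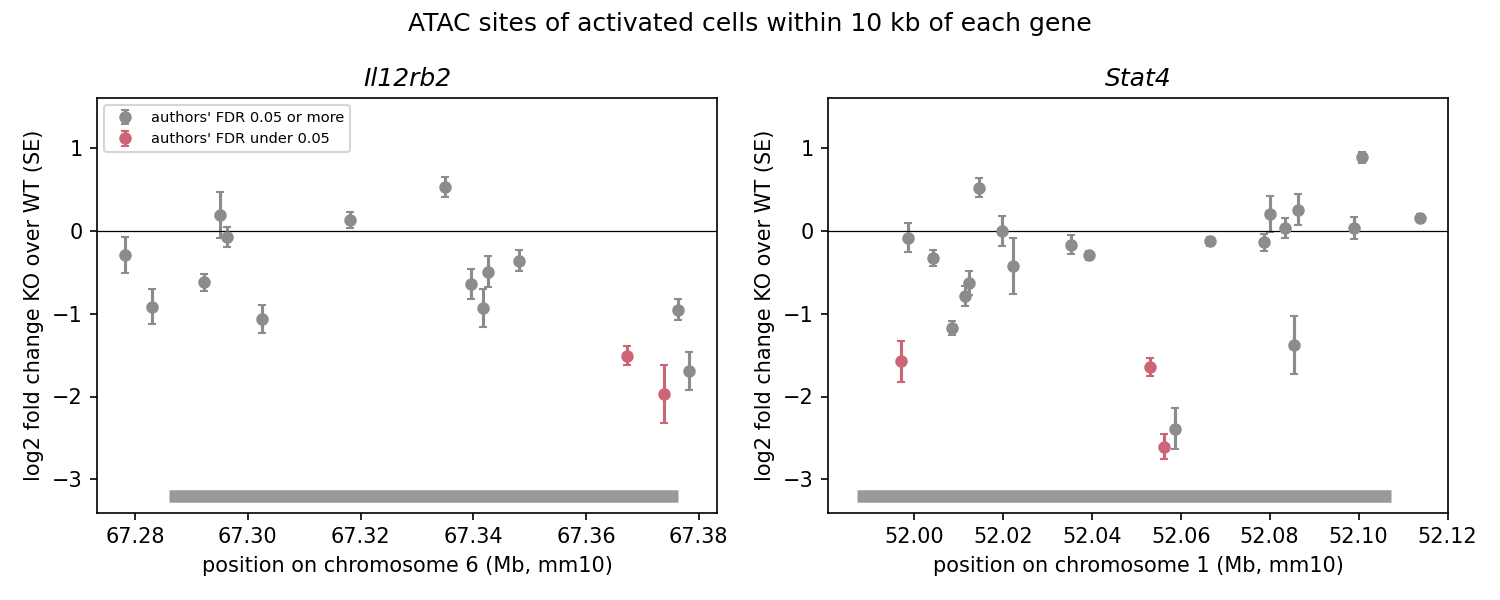
Log2 fold change of KO over WT (edgeR, with SE) of the ATAC sites of activated cells within 10 kb of Il12rb2 (left, chromosome 6) and Stat4 (right, chromosome 1) against position in Mb (mm10); grey bars are the gene spans and coloured sites have an authors' FDR under 0.05. The 2 coloured sites at Il12rb2 and the 3 at Stat4 lie below 0.

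In naive cells the authors' deposited table called 19 sites, 12 higher and 7 lower in KO. The 2 with the largest fold lay within Cd4, the gene of the coreceptor used to sort the cells, at 124879828 to 124880228 on chromosome 6, with 39.5 ± 9.31 CPM in KO against 0.320 ± 0.119 CPM in WT, and at 124883400 to 124883800, with 46.8 ± 8.99 against 1.27 ± 0.161 CPM (SD, n = 3). Cd4 RNA was at 1031 ± 23.7 CPM in naive KO and 1088 ± 60.5 CPM in naive WT cells (adjusted p = 1). Other higher sites of the authors' deposited table lay in Gm4951 and Gm4841 on chromosome 18, at log2 differences of 5.03 and 4.17, and the lower ones included sites in Khdrbs3 at -3.33 and Iqch at -4.04. The site in Iqch, at 0.0614 ± 0.0255 CPM in KO against 0.947 ± 0.779 CPM in WT, was not tested in the main edgeR fit. It did not pass the edgeR test without a filter or with any 1 KO library left out (adjusted p up to 0.400). All 19 sites had an absolute log2 difference of at least 1 in the authors' deposited table. The edgeR test on the deposited counts called 1565 of 74371 sites, 958 lower and 607 higher, of which 140 and 210 by at least 1. The count of 1565 became 6171 with a replicate block, 949 and 1031 without WT replicate 1 and 2, and 550 without KO replicate 3. Of the 19 sites, 6 were also called in activated cells in the authors' deposited table, all in the same direction.

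**Figure D5:**
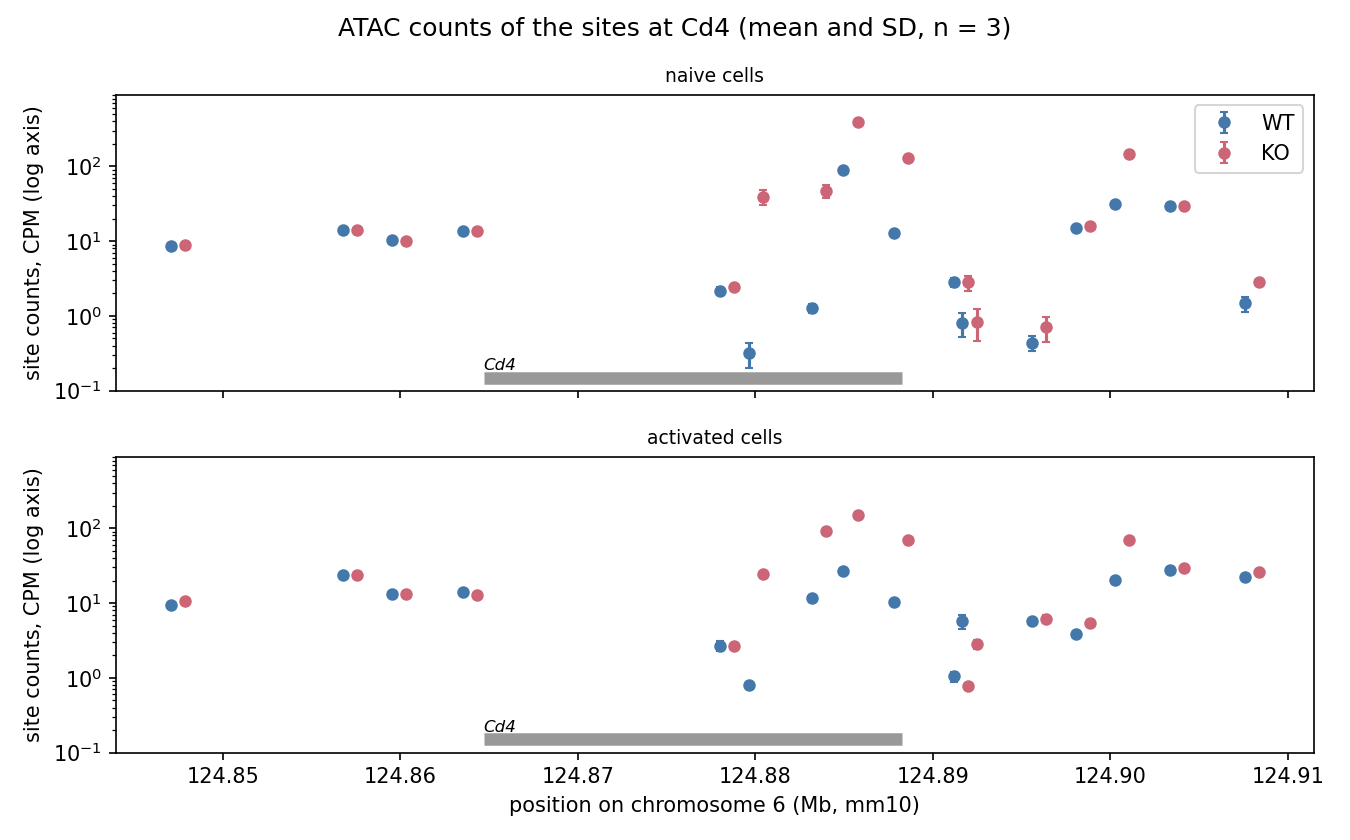
ATAC counts in CPM (log axis) of the sites within 20 kb of Cd4 against position on chromosome 6 in Mb (mm10), in naive (top) and activated (bottom) cells; points are means and error bars the SD over 3 libraries. The 5 sites that are higher by more than 1 on the log2 scale in naive KO cells have log2 fold changes of 2.12 to 6.97 there and of 1.79 to 4.95 in activated cells; a sixth past the edgeR test in naive cells, at 124907789, has 0.92 and 0.21.

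Chromatin and RNA changes were then compared gene by gene. Among genes with a site lower in activated KO cells in the authors' deposited table within 10 kb, 387 of 1824 had lower RNA, or 21.2%, against 6.94% of the other genes (Fisher's exact test, two-sided, odds ratio 3.61, p = 5.96e-68). They included Il12rb2, Stat4, Gzmb, Runx3 and Bhlhe40 of the Th1 list and 13 cAMP-CREB target genes, among them Crem, Nr4a1, Fosl2, Dusp4 and Pde4d. For higher sites 25 of 205 genes had higher RNA (odds ratio 2.25, exact p = 0.000506), and the odds ratio was 1.85 (exact p = 0.137) at an authors' FDR under 0.01. In naive cells only 2 genes had a lower site, of which Pde3b had lower RNA (odds ratio 889, exact p = 0.00242), and at an authors' FDR under 0.01 no gene had both. Of 4 genes with a higher site in naive KO cells 3 had higher RNA (odds ratio 2888.5, exact p = 7.05e-09). The higher sites of naive cells lay in a few clusters, so genes near them are not independent and this p can be too small. Gm4951 and Gm4841, for example, are neighbours on chromosome 18, at 60212004 to 60248440 and 60268301 to 60273267.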

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

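All tests of explanations and all counts of other splits below were chosen after the results were seen; the interaction test was chosen before the data were examined.

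The genotype difference in activated cells differed from that in naive cells for 443 genes by the interaction test, and this difference between states is what singled out the values here. Among named genes with a lower difference in activated cells, the values on the log2 scale were -2.23 for Stat4, -3.38 for Il12rb2, -1.58 for Prkaca, -1.79 for Crem, -1.15 for Nr4a1, -6.33 for Ramp3, -5.27 for Ntrk3, -4.66 for Tent5a, -3.48 for Klf4 and -3.21 for Dusp4. Klf4, a quiescence factor, and Dusp4 belong to the cAMP-CREB target genes. Those with a higher difference were Olfml2a at 4.47, Kifc3 at 2.29, Pdk2, a kinase that restrains pyruvate oxidation, at 2.14, the costimulatory receptor gene Slamf6 at 1.72, Palm3 at 1.71, Ramp1 at 1.68, Il18r1 at 1.61 and Ift74 at 1.59. For Olfml2a the SE was 1.00, and the difference in activated cells alone was 2.28. Perp had -7.41 and Smim3 -5.60, but both had 0 counts in every naive WT library, so these fitted values depend on the prior count and are no bound. With 1 library left out Il12rb2 lost its call in 5 of 12 fits (without naive WT replicates 1, 2 or 3 or naive KO replicates 1 or 3, adjusted p up to 0.166), and Palm3 in 6 (without naive KO replicates 1 or 2, activated WT replicates 1 or 3 or activated KO replicates 1 or 2, adjusted p up to 0.103). So did Perp, without naive KO replicate 1 or activated KO replicate 2. Smim3 lost its call without naive WT replicates 1 or 2 or naive KO replicates 2 or 3. Palm3, at 84021157 to 84030671 on chromosome 8, lies near Prkaca, at 83972978 to 83996444, and a local effect was not tested.

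The gene lists past the interaction test all had lower differences in activated KO cells by camera. Adjusted p was 8.3e-17 for cAMP-CREB target genes, 6.73e-06 for T cell activation, 1.27e-05 for glycolysis, 0.000115 for Th1, 0.000554 for homing and chemokine receptors, 0.000801 for phosphodiesterases and cAMP production, 0.00125 for naive and quiescence, 0.00596 for cytokines, 0.00625 for IL-2 STAT5 targets, 0.00986 for IL-12 and IL-18 receptor signalling, 0.015 for memory and effector CD4 and 0.0277 for Treg, which lost its call without naive KO replicate 3, activated WT replicate 2 and activated KO replicates 1 or 3 (adjusted p up to 0.107). With an estimated correlation the cAMP-CREB targets and T cell activation passed, at adjusted p = 0.00187 and 0.011. The other lists had adjusted p from 0.058, for homing, to 0.279, for IL-2 STAT5 targets, with an estimated correlation.

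Sites at Cd4 were far higher in KO than in WT, with 5 of the 16 sites within 20 kb past the edgeR test and higher by more than 1 on the log2 scale in naive cells. A sixth passed the test at 0.92 and is counted with the others below. Library depth or scaling is argued against by the lowest log2 ratio of these sites over both states and all scalings, 1.79, while the other 11 sites had a median of 0.06. Higher transcription of the resident gene is argued against by Cd4 RNA, whose naive log2 fold change had an upper 95% limit of 0.0744. Extra copies of pieces of the Cd4 locus in the KO animals, as Cre transgenes driven by Cd4 sequences carry, may explain the sites. Those picked in naive cells were all higher by at least 1.79 in the separate activated libraries. That check cannot tell extra copies from another lasting difference at these sites. The labels name no transgene, so extra copies stay a hypothesis.

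Class II genes were higher in activated KO cells, led by Cd74. RNA from B cells is argued against as the whole cause by Ighm, Igkc, Ighd, Cd79a, Cd79b and Ms4a1, whose median gain was 0.492% of the gain of Cd74. Each of the 6 was higher in KO, however, with Ms4a1 at 1.05 against 0.0906 CPM, Cd79b at 4.31 against 1.91, Igkc at 0.725 against 0.327, Cd79a at 0.554 against 0.207 and Ighd at 1.88 against 1.64 CPM. Ighm stood at 170 against 112 CPM, a gain of 57.7 CPM against 138 CPM for Cd74, and it carried most of the rise of the summed B cell markers from 117 ± 11.8 to 180 ± 14.4 CPM (SD, n = 3). Igkc, the light chain gene that B cells would bring with it, gained 0.398 CPM. A small number of B cells in the KO libraries stays open. A single library is argued against by the lowest Cd74 log2 fold change with any library left out, 1.09. Expression by the KO T cells themselves, or by another class II-positive cell that passed the sort, remains open, and no biological explanation was tested.

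A split of the naive RNA libraries that puts WT 1, WT 2 and KO 1 against WT 3, KO 2 and KO 3 called 345 genes, against 29 for the genotypes, which points to a structure of these libraries other than genotype. Sex of the animals would not by itself part WT 2 from WT 3, which are both female and lie on opposite sides of this split. Over 62 genes picked without WT 2 and WT 3, these libraries differed in the direction of the split for 42, with a median log2 difference of 0.19. That median fell short of the limit set for this check, so the check cannot tell whether sex is the whole cause. A share of sex cannot be told apart, since only WT 2 parts sex from this split. Over the 345 genes, replicate 1 of the activated libraries, the male one, differed from the others by medians of 0.02 in WT and 0.06 in KO. A trend with gene length cannot be told apart, since rho across genes was 0.193 for this split but reached 0.25 in size for another split that called fewer genes. The genes higher in WT 3, KO 2 and KO 3 had a median span of 7.31 kb, those higher on the other side 55.6 kb, and all tested genes 21.5 kb. RNA quality or preparation stays open, and the labels record neither. WT 3, KO 2 and KO 3 had 13545 to 13822 genes detected, against 13841 to 14036 on the other side. Rn18s, a ribosomal RNA gene, held 0.0606% of the counts in WT 3 and 0.0279% in KO 2, but 0.0174% in KO 3, within the 0.0116% to 0.0198% of the other side. The chi-square per degree of freedom was 17 and 19 between WT 3 and the other WT libraries, against 7.06 between those. Among KO libraries it was 11 between KO 1 and KO 2 and 4.84 between KO 1 and KO 3, on opposite sides. It was 6.73 between KO 2 and KO 3, on the same side, so the KO values do not follow the split.

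Other splits of the same libraries were fitted for each result. These fits had no replicate block, so they do not allow for a likeness of libraries with the same replicate number. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The naive comparison had 29 genes against 345 in the highest other split, so 2 of 10 splits gave as many. The activated comparison had 1789 genes, WT activation 9897 and KO activation 9837, each against 0 in the highest other split, and forskolin had 4484 against 3, so 1 of 10 splits gave as many in each. Lists past the test numbered 8 against 5 in naive, 12 against 8 in activated and 8 against 6 in forskolin-treated cells, so 1 of 10 splits gave as many in each. For the activation of WT cells and of KO cells the real split gave 13 lists and the highest other 15, and 5 of 10 splits gave as many in either. ATAC sites by the edgeR test numbered 1565 against 23 in naive and 37350 against 0 in activated cells. For the interaction 40 splits were fitted, and 5 gave at least the real 443 genes, so chance cannot be excluded by this count. The 4 others all kept the activated libraries in their genotypes and mixed naive ones, with 459 to 1663 genes. The highest lay along the split of naive libraries described above. The remaining 35 gave 0 to 3, and they mixed the activated libraries, which broke up the genotype difference that the 4 kept. The outcome thus followed whether activated libraries kept their genotypes, so these splits cannot decide on chance. The 12 lists of the interaction were reached by 1 of 40 splits, a share under 0.05, but with 11 in the highest other. The margin of 1 list is lost without naive KO replicate 3, activated WT replicate 2 or activated KO replicate 3, which leave 11. With that margin and the same splits, the count of lists cannot exclude chance either.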

How the results depend on the processing

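The edgeR tests of ATAC counts and their alternatives, except leaving out libraries, were chosen after seeing the data; the other alternatives were chosen before the data were examined. At FDR 0.01 the counts were 14 genes in naive cells, 967 in activated cells and 217 for the interaction. With a minimum absolute log2 fold change of 1 they were 14, 436 and 152, with 5602 for WT activation, 5450 for KO activation and 512 for forskolin. These follow from the stricter thresholds. DESeq2 gave 59 genes in naive cells, and the cause was not tested. Lists past camera with an estimated correlation numbered 0 in naive cells, 2 in activated cells, 3 with forskolin and 2 for the interaction. The cause was not tested. Fry, which tests another hypothesis, gave 20 lists with forskolin. Against the 19 and 5713 sites of the authors' deposited table, limma gave 1269 and 38801 and edgeR 1565 and 37350. Limma with a replicate block gave 4922 and 45351. All 19 and 5713 sites differed by at least 1 on the log2 scale, a limit not set for these other counts. The cause of the gap was not tested. At an FDR under 0.01 the authors' deposited table held 3257 sites in activated cells. The edgeR counts were 658 and 24692 at FDR 0.01, 350 and 10423 with a minimum fold, and 6171 in naive cells with a replicate block. The odds ratio of ATAC and RNA in naive cells was 0 at an authors' FDR under 0.01, where 1 gene with a lower site was left, and that for higher sites in activated cells was 1.85.

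With each library left out in turn, genes past the test ranged from 11 to 38 in naive cells, 1151 to 1393 in activated cells, 9702 to 9966 for WT activation, 9598 to 9721 for KO activation, 290 to 472 for the interaction and 3915 to 4176 with forskolin. Lists ranged from 7 to 11 in naive cells, 11 to 14 in activated cells, 6 to 10 with forskolin and 11 to 14 for the interaction, and edgeR sites from 550 to 2207 in naive and 28662 to 38104 in activated cells. Without naive WT replicate 3 the naive lists of cholesterol and lipid synthesis and of oxidative phosphorylation changed direction, at adjusted p of 0.761 and 0.0269, against 7.79e-05 and 0.0154 without KO replicate 2, and the cause was not tested. Counts of 11, 17 and 12 in naive cells came without WT replicate 2, KO replicate 1 and KO replicate 3. Of 9036 values for named genes 8710 kept their side of the threshold, 317 lost and 9 gained a call. None that passed in the main fit or the alternative reversed direction. Direction was not checked for values that passed in neither. For lists 410 of 515 were kept, 61 lost, 42 gained and 2 reversed, and for sites 393 of 397 were kept and 4 lost.

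Correlations between libraries of the same replicate number did not all pass 0.1 for naive KO with WT RNA (0.00363 to 0.409), WT activation (0.0967 to 0.267) and forskolin (0.0776 to 0.217). Library totals without further scaling moved the median of all genes by 0.12 in WT activation and 0.13 in KO activation on the log2 scale. In simulated data the share of 1.5-fold changes found was 65.7% in naive, 62.7% in activated and 69.7% in forskolin RNA. In ATAC sites it was 43.3% in naive and 50.8% in activated cells, each share of 66 or 67 changes. The simulated counts were independent, with a spread that followed the mean level alone and no sex or other library structure. Only features above a minimum level were changed. These shares may thus overstate what can be found in the real libraries. Depth limits what can be said of Ifng in naive cells and of other genes with few counts. Not run were the CREB motif test, the window of 1 kb around the transcription start, and the comparison of site overlaps, since both tables hold identical sites. Other pseudocounts did not apply to counts.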

Other observations

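The checks of the forskolin libraries and the edgeR test of sites in this part were chosen after the results were seen; the gene and list tests were chosen before the data were examined.

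Lineage lists other than Th1 held changes in both directions in activated KO cells. Of 13 Treg genes 4 were lower and 3 higher, with Tigit, an inhibitory receptor gene, at 5.52 ± 0.840 CPM in KO against 34.3 ± 4.14 CPM in WT (SD, n = 3). Of 11 Tfh genes 3 were lower and 3 higher, with Slamf6 higher at 69.0 ± 2.49 CPM against 18.6 ± 5.83 CPM. Of 8 Th17 genes 3 were lower and 2 higher, with the transcription factor genes Stat3 at -1.11 ± 0.08 and Batf at 0.84 ± 0.11 on the log2 scale. Of 7 Th2 genes 4 were lower and 1 higher, among them Gata3, the Th2 master regulator gene, at -0.49 ± 0.11, and the chemokine receptor gene Ccr8 at -1.88 ± 0.22. None of these lists passed the camera test in that comparison.

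With forskolin, Foxp3, the regulatory T cell transcription factor gene, stood at 40 ± 3.20 CPM in KO against 16.4 ± 1.70 CPM in WT, and Il2ra at 141 ± 17.7 against 23.5 ± 1.93 CPM (SD, n = 3). The pro-apoptotic gene Bcl2l11 was lower at 155 ± 7.76 against 451 ± 6.88 CPM. Of 16 genes of p53 targets and apoptosis 9 were higher and 2 lower, a list that did not pass the test (camera adjusted p = 0.0671).

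KO replicate 1 of the forskolin libraries had 16293 genes detected, and 15286 after all libraries were thinned to 7665955 counts, against at most 14602 in the other libraries. It was highest for 10 of 25 markers of other cell types, with H2-Aa at 10.8 CPM against 1.48 and 0.540 CPM in the other KO libraries, and Lyz2, a myeloid gene, at 1.18 CPM. The median log2 ratio of these markers to the other KO libraries was 0.02, and that of KO replicates 2 and 3 to WT was 0.57.

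In naive cells, ATAC sites by the edgeR test formed clusters of higher sites in KO. On chromosome 3 between 60 and 65 Mb, 22 of 95 tested sites were higher and 0 lower, and on chromosome 18 between 60 and 61 Mb, 14 of 72 were higher and 0 lower. The site on chromosome 3 at 60765094 to 60765494 had a log2 difference of 4.70 in the authors' deposited table.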
